A study of Saccharomyces cerevisiae with 21 samples.

How the data were processed

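RNA was measured by sequencing in 21 libraries of budding yeast (Saccharomyces cerevisiae) in the W303 background. The libraries fall into 7 groups of 3: wild type, and strains in which UPF1, UPF2, UPF3, DCP1, DCP2 or XRN1 was deleted. Per the labels' protocols, the cells grew in rich medium and were harvested in growth phase, RNA was taken up with hot phenol, ribosomal RNA was removed from total RNA, and libraries were made with an Illumina kit. Nothing in the sources used here says that the replicates of a strain came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

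Per the submitters' processing notes, FastQC, Bowtie, RSEM and DESeq were used with genome build R64. Their versions, their settings and whether counting used the strand of a read are not given in the sources used here. The authors deposited 6 tables, each of which compares 1 deletion group with the wild-type group over 7473 features. Per the file headers, the authors' tables give a normalised signal per group, which is the mean over libraries of the read count divided by a size factor. The authors' deposited fold change is on the log2 scale, deletion over wild type, per the file headers. The authors' deposited p-value for each feature stands beside their adjusted p, per the file headers. Several genes have a spliced and an unspliced form, which the authors' counting with RSEM could split only as an estimate.

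The tables hold group means and no value per library, so each level below is the authors' mean and has no standard deviation. In each table the low values, searched up to 5, were whole reads divided by 3 size factors: 100% of them came out whole within a tolerance of 1e-06. The size factors ran from 0.622 to 1.80, and libraries of 1 group differed in depth by 1.04 to 1.65 times. A mean over 3 libraries does not give the reads of each library back, so no count test was run here. The tables were scaled separately, and the ratio of wild-type means between tables deviated from 1 constant by at most 2.09%, so every test was made within a table or on folds.

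A feature was called changed where the authors' adjusted p was below 0.01. The standard error of a fold was taken as its size divided by the normal quantile of the authors' two-sided p. The difference between 2 strains was tested with both errors added in squares, and p was adjusted by the method of Benjamini and Hochberg with a threshold of 0.01. This leaves out the covariance that comes from the shared wild type, which makes the test strict, and an alternative set the correlation of the errors to 0.5. Overlaps and covariances between strains were set beside 100 simulated comparisons of unchanged groups against shared wild-type libraries, and beside the overlap that independent lists would have.

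Gene lists, 42 in all, were fixed from textbook knowledge. Each was tested in each strain with limma's cameraPR on signed normal scores, with a preset inter-gene correlation of 0.01. The p-values were adjusted over 252 tests with a threshold of 0.05. The correlation could not be estimated from group means, so each test was repeated with a correlation of 0.05: of 136 calls, 91 held and 45 did not. Counts of members past the threshold use the authors' adjusted p, and counts "adjusted over the list alone" use the authors' p adjusted within the list. Among the called lists, the median, the mean and the test did not differ in sign in any case once the median of all features was subtracted. Feature classes were compared with 2-sided Fisher's exact tests. Features are not independent replicates.

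Gene names, positions and sequences come from NCBI RefSeq's annotation of build R64, the build the submitters name. A locus tag matched 6318 of the identifiers, and 1155 did not match, mostly those of noncoding RNAs and of reading frames outside the annotation. Where over a 0.3 share of a gene's 50-base words occurs elsewhere in the genome, or where features have identical values, the counting could not tell the copies apart: 618 features are of this kind and are called near-identical copies below. Without strand, reads of overlapping genes on opposite strands could not be told apart either.

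The named genes follow a rule: in each strain the 6 deleted genes, and the 10 largest increases and 10 largest decreases among features past the threshold with a mean of at least 50 and a finite fold, taking the form with the larger mean of each gene. From each list or class the rule takes the 4 members with the smallest adjusted p, and all members of the lists of classic NMD substrates, frameshift genes, W303 markers, decay factors and mating type. It adds the 20 features with the largest smallest-of-3 fold among those higher in all 3 UPF strains by the same mean limit, and the 5 largest differences each way in each pair of strains. Many members it takes from lists and classes are left out for length. Of the other features 1 is not reported here, and the flagged differences pass over it to the next in rank, a choice made after the data were seen. Members named beside a count of 5 or fewer, the flanking genes of deleted genes and everything about chromosome III lie outside the rule and were chosen after their values were seen. The groups, tests, lists, named-gene rule and most alternatives were set before the data were examined. The alternatives were other thresholds, minimum means and folds, centred folds, other error correlations, other list tests, and lists without near-identical copies. Chosen after seeing the data were scaling to equal totals, errors taken from features of like mean, and counts without the libraries labelled UPF2 or DCP2 deletion, without mating-type genes or without chromosome III, common features without near-identical copies, lists without the deleted genes, and simulated lists as long as the observed ones.

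The tests were checked on simulated data. With 6238 features in a simulated strain and wild type of 3 libraries each, 22% of features changed 1.5-fold were recovered, 78.7% of those changed 2-fold and 98.7% of those changed 4-fold, and 0.0166% of unchanged features were called. Between 2 simulated strains that share the wild type, 20% of differences of 2-fold and 80% of those of 4-fold were recovered, and 80% and 84% with errors correlated at 0.5, which called 0.0162% of unchanged features. Simulated lists of 30 genes shifted by 1 standard error were called in 22.5% of cases and those shifted by 2 in 100%. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used, with R 4.3.3 and limma 3.58.1.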

Results

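The data describe RNA in yeast that lacks single parts of the nonsense-mediated decay (NMD) or general messenger RNA decay machinery. Upf1, Upf2 and Upf3 act in NMD, which removes transcripts whose translation ends too early. Dcp1 and Dcp2 form the enzyme that removes the cap of a messenger RNA, and Xrn1 degrades the decapped RNA from that end. Each of 6 deletion strains, in 3 libraries each, was set against the same wild type in 3 libraries. Of 7473 features per table, 7364 to 7376 had a test. On the log2 scale the authors' mean normalised counts summed over features differed from those of the wild type by -0.22 to -0.35 in the UPF tables, by -0.77 in DCP1, by -0.73 in DCP2-labelled libraries and by -1.14 in XRN1. The median fold over features with a mean of at least 50 was -0.12 in UPF1, -0.11 in UPF2-labelled libraries and -0.10 in UPF3 and ran from -0.01 to 0.03 in the decay strains. Gene lists are described with the number of members past the threshold over all features, and the number adjusted over the list alone is given where it differs in the direction described.

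The deleted gene itself was nearly absent in 4 of the 6 strains. The authors' deposited tables put NAM7, the name under which UPF1 is listed (chromosome XIII, 426712 to 429627), at an authors' mean of 88.6 in its own deletion, 0.571% of the wild-type 15515. In the authors' deposited tables UPF3 (chromosome VII, 634304 to 635467) stood at 0.392% of the wild type in its deletion, DCP1 (chromosome XV, 44938 to 45633) at 0.607% and XRN1 (chromosome VII, 175527 to 180113) at 0.344%. The other 2 strains went the other way. The authors' deposited table for UPF2 lists NMD2, the gene of Upf2 (chromosome VIII, 252374 to 255756, 2 exons), at 58506 against 4821 in the wild type, 12.1-fold higher (authors' adjusted p 3.53e-48). In the authors' deposited table its unspliced form fell by 6.40 on the log2 scale to 1.18% of the wild type. The authors' deposited table for DCP2 lists DCP2 (chromosome XIV, 402652 to 405564) at 11933 against 7821, 1.53-fold higher (authors' adjusted p 0.00606). In both groups the level of the targeted gene goes against the label. They are therefore called the libraries labelled UPF2 or DCP2 deletion, or UPF2-labelled and DCP2-labelled. Each direction drawn from them is that of libraries so labelled. Which part was removed is not given in the sources used here.

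Some genes beside the deleted ones differed too, 5 of 12 flanking genes in the strain of their neighbour, and were looked up after the values were seen. In the libraries labelled UPF2 deletion, the authors' deposited table gave PTC7, on one side of NMD2, a log2 fold of -1.02 and YHR078W, on the other, 1.88. In the authors' deposited tables for the UPF1 and UPF3 deletions, YHR078W had log2 folds of 0.49 and 0.41, below the threshold. The authors' deposited tables gave ENV11, beside UPF3, 1.39 in the UPF3 deletion and 1.01 in XRN1. In the authors' deposited tables ISF1, beside NAM7, had -1.03 in the UPF1 deletion, but passed in 4 other groups too, as at -0.82 in UPF3 and 1.32 in DCP1, and MLS1, beside DCP2, had 0.97 in the libraries labelled DCP2 deletion, but also 1.77 in DCP1. SEC14, SMD1, GRE2, SPT20, NCS2, BUD13 and NUP49 did not pass in the strain of their neighbour.

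**Figure D1:**
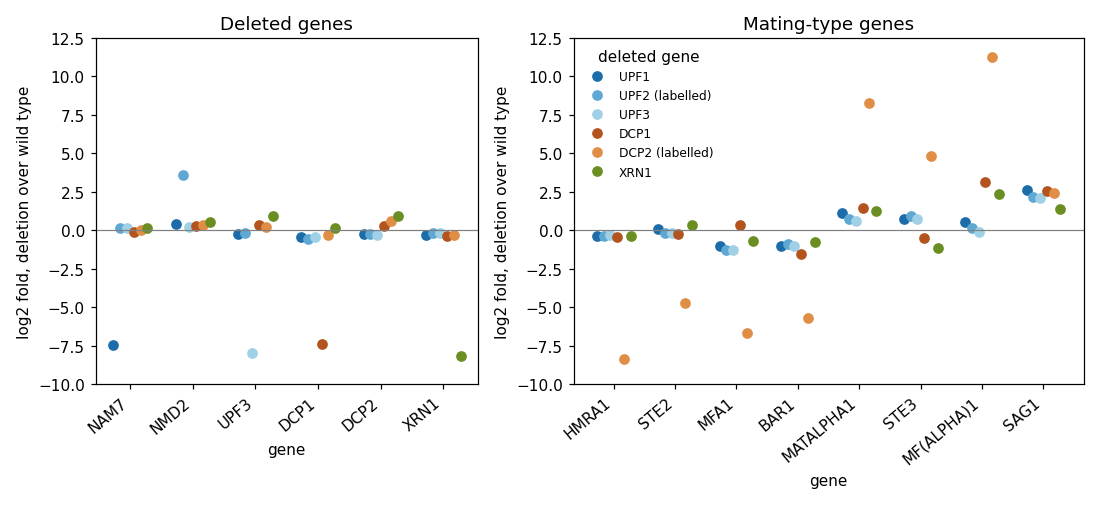
Log2 fold (vertical axis, deletion over wild type, authors' values) of the 6 deleted genes and of 8 mating-type genes, one dot per deletion strain. NAM7, UPF3, DCP1 and XRN1 lie at -7.36 or below in their own strains while NMD2 and DCP2 lie above 0 in the libraries labelled with their deletion, where for DCP2-labelled libraries HMRA1, STE2, MFA1 and BAR1 are at -4.71 or below and MF(ALPHA)1 is at 11.25.

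The UPF1 deletion asked which transcripts NMD keeps low. Far more RNAs rose than fell: 989 features were higher and 49 lower than in the wild type, with a median fold of 2.69 among those higher, and 95.3% of the changed features went up. Rankings here take features with a mean of at least 50 and a finite fold, 1 form per gene. Among these the authors' deposited table put AAD15 highest, with a log2 fold of 3.86 (a gene with near-identical copies), then HIS3, an enzyme of histidine synthesis, with 3.85, the unannotated reading frame YOR203W with 3.77 and PET18 with 3.67. The authors' deposited table also gave YHL037C 3.58, YJL135W 3.42, YOR008W-B 3.40, ADE2, an enzyme of adenine synthesis, 3.39, YOR072W 3.36 and YOR161W-B 3.32. Below the wild type, apart from NAM7 itself at -7.45 (authors' adjusted p 2.83e-164), the authors' deposited table listed the small nucleolar RNA SNR59 at -3.17 and FET3, the iron oxidase of high-affinity uptake, at -2.64. The sulfate permease genes SUL2 and SUL1 stood at -1.47 and -1.24, PHM6, a gene of the phosphate response, at -1.40 and FLP1, the recombinase of the 2-micron plasmid, at -1.35 in the authors' deposited table. YAR070C (-1.91), the unspliced form of tL(CAA)D (-1.48) and TAR1 (-1.39, near-identical copies) were also among the largest decreases in the authors' deposited table, and these 3 no longer passed when the table was scaled to equal totals. Equal totals gave 1466 features higher and 14 lower.

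In the libraries labelled UPF2 deletion, 1118 features were higher and 165 lower, a share of 87.1% higher and a median fold of 2.48 among them, although NMD2 RNA was raised in these libraries. By the same limits the authors' deposited table again put AAD15 (3.74), NMD2 itself (3.60), HIS3 (3.60), PET18 (3.52), YOR203W (3.48) and YOR161W-B (3.40) highest. Next in the authors' deposited table came PEX9, a receptor for import into peroxisomes, with a log2 fold of 3.34, ADE2 with 3.31, YPS5 (near-identical copies) with 3.27 and YHL037C with 3.25. Apart from the unspliced form of NMD2 the largest decreases in the authors' deposited table were YHR214C-B (-4.38), FET3 (-2.50), YHR214W-A (-2.29), YHR054C (-2.25) and YHR214W (-2.10), where YHR214C-B, YHR054C and YHR214W have near-identical copies. YAR070C (-1.96), the unspliced form of RPS22B (-1.64), PHO12 (-1.58, near-identical copies), HPF1 (-1.5) and MFA1, a mating pheromone gene (-1.28), followed in the authors' deposited table. HPF1 no longer passed with equal totals, which gave 1851 higher and 27 lower.

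The UPF3 deletion had 1013 features higher and 87 lower, 92.1% of them higher, with a median fold of 2.51 among the higher. The authors' deposited table listed YOR161W-A at 4.75, YOR161W-B at 3.91, HIS3 at 3.71, YOR203W at 3.68, AAD15 at 3.63 and PET18 at 3.61. YHL037C (3.50), PAU4 (3.42, near-identical copies), ADE2 (3.38) and the maltose permease gene MAL31 (3.26) completed the largest increases in the authors' deposited table. Beyond UPF3 at -8.00, the authors' deposited table had FET3 at -2.14 and 3 genes of the 2-micron plasmid, FLP1 at -2.13, REP1 at -1.70 and REP2 at -1.52. SOM1 (-1.79), YGR035C (-1.56), PHM6 (-1.55), HPF1 (-1.43) and the unspliced form of RPS22B (-1.43) were the other large decreases in the authors' deposited table. With equal totals 1400 features were higher and 22 lower.

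**Figure D2:**
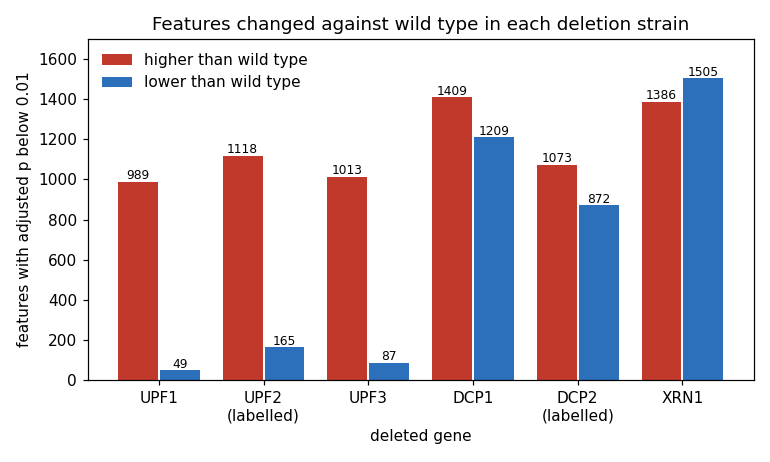
Number of features (vertical axis) with an authors' adjusted p below 0.01 in each deletion strain, higher (red) or lower (blue) than wild type. In the UPF strains 989 to 1118 features were higher and 49 to 165 lower, whereas DCP1, DCP2-labelled libraries and XRN1 had 872 to 1505 lower.

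Most of these increases were common to the 3 UPF strains. A total of 907 features were higher in all 3 groups, the libraries labelled UPF2 deletion included, which is 76.5% of the 1185 higher in at least 1, and 662 of them were at least 2-fold higher in each. By class they were 768 coding genes without introns, 56 unspliced forms, 51 reading frames outside the reference annotation, 10 spliced forms, 9 joined reading frames, 8 pseudogenes and 5 noncoding RNAs. The 20 with the largest smallest fold and a mean of at least 50 began with AAD15, HIS3, PET18, YOR203W, YOR161W-B, ADE2 and YHL037C, and went on with YOR072W, YOR008W-B, YJL215C, YLL059C, YPS5 and PAU4. PEX9, the maltose transporter genes MAL31 and MAL11, the sporulation gene SPS4, the urea permease gene DUR3, DAL7 of allantoin use and the iron reductase gene FRE2 were the rest. YOR161W-A, under that mean in UPF1 and UPF2-labelled libraries, had 4.11, 4.0 and 4.75 in the authors' deposited tables for UPF1, UPF2-labelled libraries and UPF3. All 3 groups shared 29 lower features.

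Independent lists would have shared 20.7 higher and 0.0131 lower features in all 3 groups, and simulated groups with no effect shared 0 at most in 100 draws, which says little, as few of their features pass. Lists as long as the observed ones from the top of such groups shared 203 on average and 233 at most. The folds correlated across 6212 features, which are not independent replicates, with r of 0.96 for UPF1 and UPF2-labelled libraries, 0.92 for UPF1 and UPF3 and 0.93 for UPF2-labelled libraries and UPF3, where the shared wild type alone gave 0.498 in the first pair. Covariances were 0.528, 0.484 and 0.485 against simulated values of 0.0258, 0.0271 and 0.0244. Part of the excess may come from the shared controls, which group means cannot split. Of the 907 features, at least 80 have near-identical copies and at least 18 overlap an opposite-strand gene. The 51 frames outside the annotation have no position to check.

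Tests of the difference found few features that set the UPF strains apart. UPF1 differed from the libraries labelled UPF2 deletion at 5 of 7132 features, UPF1 from UPF3 at 5 of 7136, and the libraries labelled UPF2 deletion from UPF3 at 11 of 7144, and these include the deleted genes. With errors correlated at 0.5 for the shared wild type the counts were 12, 12 and 20, and with errors from features of like mean 13, 22 and 47. None of the 907 common features was among them by the first test, a normal test on the authors' folds, and 2, 4 and 1 were at a correlation of 0.5, with 31, 35 and 36 of all features in the 3 pairs at an unadjusted p under 0.05 in the first test. NMD2 was lower in UPF1 than in the libraries labelled UPF2 deletion by a log2 difference of -3.20 (SE 0.40, adjusted p 4.08e-12 in the test of the authors' folds), and YHR078W by -1.39 (SE 0.27). REP2, a partition gene of the 2-micron plasmid, was higher in UPF1 than in UPF3 by 1.66 (SE 0.26) and SOM1 by 1.81 (SE 0.34), while ENV11 was lower by -1.47 (SE 0.28). Between the libraries labelled UPF2 deletion and UPF3, YHR214W differed by -2.63 (SE 0.42). In simulations the first test found 20% of 2-fold differences and that at a correlation of 0.5 found 80%, so the first misses many differences of that size.

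Transcripts long used as examples of NMD substrates rose together. Of 25, 16 rose in UPF1, 18 in the libraries labelled UPF2 deletion and 17 in UPF3 (17, 18 and 17 adjusted over the list alone). In UPF1, UPF2-labelled and UPF3 order, the authors' deposited tables gave the telomere genes EST2 log2 folds of 2.93, 2.78 and 2.70, STN1 2.80, 2.78 and 2.75, TEN1 1.81, 1.66 and 1.73, EST1 1.79, 1.75 and 1.74 and EST3 1.51, 1.48 and 1.55. CPA1, whose leader encodes an arginine attenuator peptide, had 1.66, 1.70 and 1.69 in the authors' deposited tables, CTF13 of the kinetochore 1.39, 1.33 and 1.20 and FZF1 1.32, 1.29 and 1.26. ALR1, PGA1, COX19, SAS2, BUB3, REV7, EBS1 and DAL7 also rose in the 3 groups. ADR1 rose in the last 2 and PPR1 in the libraries labelled UPF2 deletion, where YRA1 fell (-0.62 in the authors' deposited table). Adjusted over the list alone, YRA1 and GAL11 fell in UPF3, while COX23, SPT10, UBP7, MER1, SSY5 and GAL11 passed over all features in no UPF strain. The list test gave adjusted p of 5.48e-13, 3.91e-12 and 1.30e-12. Of 12 telomere maintenance genes, 9 rose in each group (adjusted p 3.04e-09, 2.47e-08 and 7.66e-09), among them TEL1 and RIF2, and RAP1 fell in the last 2.

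The marker genes that carry mutations in W303 rose except for URA3. The ADE2, CAN1 and TRP1 alleles of this background hold nonsense mutations, HIS3 and LEU2 frameshifts and URA3 an amino acid change. Of the 6, 5 rose in each UPF group (list adjusted p 1.13e-13, 2.33e-14 and 1.12e-15). The authors' deposited tables gave CAN1 log2 folds of 2.80, 2.66 and 2.55, TRP1 2.01, 2.02 and 1.91, LEU2 1.67, 1.76 and 1.78 and URA3 -0.24, -0.20 and -0.13. Several of these genes serve as deletion markers, and the marker of each strain is not given in the sources used here. Of 3 genes read with a programmed frameshift, EST3 rose in each group, while ABP140 and OAZ1 did not pass, and the list was not called (adjusted p 0.517, 0.396 and 0.373).

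Meiosis, glucose-repressed, nitrogen, seripauperin, flocculation and COS lists were called up in at least 2 UPF groups. Of 27 meiosis genes, 17, 19 and 16 rose (19, 20 and 17 adjusted over the list alone, with list test adjusted p 6.85e-12, 1.30e-12 and 5.09e-10), RED1 of the synaptonemal complex and DIT2 in each. Of 14 meiotic genes with introns, REC107, HFM1, SPO1 and MEI4 rose in each group and SPO22 in the libraries labelled UPF2 deletion (4, 5 and 4; adjusted p 0.00861, 0.0291 and 0.00193). The call in the UPF2-labelled libraries had an adjusted p of 0.0965 at a correlation of 0.05. Of 30 glucose-repressed genes, 10, 11 and 10 rose (10, 12 and 11 adjusted over the list alone; adjusted p 0.00169, 0.000373 and 0.00134), PCK1 of gluconeogenesis among them, but against random lists matched on mean none of these 3 calls passed (adjusted p 0.105, 0.094 and 0.14). Of 23 genes of nitrogen catabolism, 8 rose in each group (and GAP1 fell in UPF2-labelled libraries adjusted over the list alone; adjusted p 0.000359, 7.90e-05 and 4.39e-05). Among 28 seripauperin and cold-shock wall protein genes, many of them near-identical copies, 17 rose in each group (adjusted p 6.54e-09, 2.71e-08 and 4.42e-08). TIR1 fell in UPF3, and in UPF2-labelled libraries adjusted over the list alone. The flocculation genes FLO5, FLO9, FLO10 and FLO11 rose in each group and FLO1 in the last 2, out of 7 (5, 5 and 5 adjusted over the list alone; adjusted p 0.00212, 0.00448 and 0.00134). COS5, COS7 and COS10 of 10 subtelomeric COS genes rose in each group and COS4 in the last 2 (adjusted p 0.0845, 0.0163 and 0.00684), and the call in the libraries labelled UPF2 deletion had an adjusted p of 0.0503 at a correlation of 0.05.

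In further lists members rose, mostly without a shift of the list as a whole. Of 27 iron regulon genes, 8 rose in each UPF group and FET3 fell (list adjusted p 0.184, 0.0524 and 0.0921), with FRE3 and FIT3 among the 8. Of 14 metal transport genes, ALR1, ALR2 and ZRT2 rose in each group and CTR3 in UPF1 (adjusted p 0.141, 0.194 and 0.176). The heat shock genes SSA3 and SSA4 rose among 24 (adjusted p 0.616, 0.925 and 0.393), FIG2, PRM1 and FUS2 among 22 pheromone response genes (STE5 too in UPF3, while FAR1 fell in the last 2; adjusted p 0.948, 0.967 and 0.938), and RNR3, RAD54 and DIN7 among 15 DNA damage genes (DDI2 too in the last 2 and MAG1 in UPF2-labelled libraries, or 6 and 5 in the last 2 adjusted over the list alone; adjusted p 0.502, 0.447 and 0.447). CPA1, INO2 and SPH1 rose among 28 genes with upstream reading frames (PPR1 too in UPF2-labelled libraries; adjusted p 0.376, 0.433 and 0.533), PRP5, PRP6, PRP18 and PRP46 among 40 spliceosome genes (PRP2 too in the first 2 and PRP38 in the last 2; adjusted p 0.626, 0.708 and 0.925), SAG1 among 4 alpha-specific genes (STE3 too in UPF2-labelled libraries; adjusted p 0.273, 0.172 and 0.291) and URA10 among 14 pyrimidine genes (PPR1 too in UPF2-labelled libraries, while URA7 fell in UPF3; adjusted p 0.938, 0.698 and 0.713). INO1 rose among 18 genes of the unfolded protein response (adjusted p 0.441, 0.938 and 0.613) and ADH4 and PDC5 among 24 glycolytic genes (1 in UPF1 adjusted over the list alone, and FBA1 fell in UPF2-labelled libraries; adjusted p 0.0506, 0.107 and 0.123). Of 26 decay factors, NMD4, EBS1 and DXO1 rose in each group, DCS2 rose and LSM3 and LSM5 fell in UPF2-labelled libraries. The decay factor list was called down in UPF1 (adjusted p 0.0206), but not without the deleted genes (adjusted p 0.697): its only lower member past the threshold was NAM7. Its median of -0.25 turned to 0.02 under equal totals, its adjusted p was 0.11 at a correlation of 0.05, and it was not called in the other two (adjusted p 0.925 and 0.155). Of 57 stress-induced genes 7, 15 and 13 rose (adjusted p 0.443, 0.0325 and 0.0381), and the last 2, though called, had adjusted p of 0.214 and 0.229 at a correlation of 0.05.

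Several lists lay lower in the UPF strains by small amounts. Of 138 ribosomal protein genes, 57 fell in the libraries labelled UPF2 deletion, while RPS22B and RPL36A fell in UPF1 and RPL29 in UPF3 (94 in UPF2-labelled libraries adjusted over the list alone, where those 3 genes did not pass). By the authors' unadjusted p under 0.05, 105, 117 and 106 passed. Their median log2 folds were -0.48, -0.55 and -0.44, and -0.21, -0.20 and -0.21 with equal totals (adjusted p 6.58e-13, 3.53e-15 and 1.15e-11). Of 10 histone genes 2, 7 and 5 fell (3, 9 and 6 adjusted over the list alone; adjusted p 0.00154, 0.000183 and 0.000864), HTA2 and HHT1 in each group. Of 15 phosphate response genes 5, 5 and 7 fell (6, 7 and 8 adjusted over the list alone; adjusted p 0.000259, 0.00138 and 4.81e-05), among them PHM6, PHO12 and the polyphosphate synthesis genes VTC1, VTC3 and VTC4. Of 24 sulfur genes 8, 6 and 7 fell (8, 8 and 8 adjusted over the list alone; adjusted p 0.000184, 0.00193 and 0.00142), STR3 among them, while MET1 rose. Of 7 a-specific genes BAR1, MFA1 and STE6 fell in each group (4, 3 and 3 adjusted over the list alone; adjusted p 0.0167, 0.00987 and 0.00456).

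Several further lists were called down in at least 1 UPF strain with few or no members past the threshold. Of 84 ribosome biogenesis genes 5 fell in UPF3, BRX1, NSR1, YTM1, CIC1 and NOG1, none of which passed adjusted over the list alone (45 at an unadjusted p under 0.05). By the authors' test 4 and 22 passed an unadjusted p under 0.05 in UPF1 and UPF2-labelled libraries. The list medians were -0.32, -0.33 and -0.51, the second of which turned to 0.01 with equal totals (adjusted p 0.000538, 8.04e-05 and 3.26e-08), and the UPF1 call had an adjusted p of 0.0591 at a correlation of 0.05. Of 35 translation factors TIF2 and CDC33 fell in the libraries labelled UPF2 deletion, but not adjusted over the list alone (19 at an unadjusted p under 0.05). By the authors' test 8 and 18 passed an unadjusted p under 0.05 in UPF1 and UPF3 (adjusted p 0.00238, 0.000264 and 0.000178). The 20 genes of the G1 to S transition had medians of -0.28, -0.31 and -0.41, the second of which turned to 0.04 with equal totals (adjusted p 0.0452, 0.0223 and 0.00626), and PCL2 and CLN1 fell in UPF3. PCL2 and CLB6 fell in UPF2-labelled libraries, but not adjusted over the list alone. At a correlation of 0.05 the first 2 of these calls had adjusted p of 0.156 and 0.0997. The 47 targets of Gcn4 were called down (adjusted p 0.0015, 0.0178 and 0.0344; at a correlation of 0.05, adjusted p 0.0516, 0.154 and 0.2), with the second median turning from -0.31 to 0.04 under equal totals, although CPA1 and ARG8 rose. ARG1 and ARG3 of this list fell in UPF1 (1 of them adjusted over the list alone). The 24 ergosterol genes were called down too (adjusted p 0.0385, 0.0171 and 0.0364; at a correlation of 0.05, adjusted p 0.156, 0.0965 and 0.153). Their medians of -0.25 and -0.34 in the first 2 turned to 0.02 and 0.01 under equal totals. NCP1 fell in UPF2-labelled libraries, but not adjusted over the list alone. For 46 respiration genes, 6 in each group at an unadjusted p under 0.05, adjusted p was 0.00335, 0.0147 and 0.0291. At a correlation of 0.05 adjusted p was 0.074, 0.138 and 0.185, and the UPF2-labelled median turned from -0.27 to 0.08 under equal totals. For 32 proteasome genes adjusted p was 0.00405, 0.00657 and 0.0128. At a correlation of 0.05 adjusted p was 0.0573, 0.0745 and 0.0997, with the UPF2-labelled and UPF3 medians of -0.24 and -0.21 turning to 0.11 and 0.01 under equal totals.

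Of 12 deadenylation genes 1, 6 and 5 passed an unadjusted p under 0.05, with list adjusted p of 0.077, 0.0311 and 0.0367, and the last 2 had adjusted p of 0.0939 and 0.102 at a correlation of 0.05. The 16 purine genes had adjusted p of 0.0364, 0.066 and 0.0691, the first with an adjusted p of 0.119 at a correlation of 0.05, and IMD3 fell in UPF3. IMD2 fell in UPF2-labelled libraries, but not adjusted over the list alone. The 22 exosome and Ski genes had adjusted p of 0.213, 0.133 and 0.0468, the last with an adjusted p of 0.167 at a correlation of 0.05. In 20 genes with regulated splicing the unspliced form of RPL22B and PRP5 rose in each group, and YRA1, RPL22A, RPS9B and PTC7 fell in UPF2-labelled libraries (5 adjusted over the list alone; adjusted p 0.747, 0.409 and 0.843). The 24 cell wall genes (adjusted p 0.261, 0.354 and 0.0806) and the 15 genes of the mitochondrial genome (adjusted p 0.0806, 0.203 and 0.535) were not called.

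Unspliced forms were over-represented among the increases of the UPF strains. In UPF1 72 of 292 unspliced forms were higher and 2 lower (24.7%, odds ratio 2.20, Fisher's exact p 1.53e-07), in the libraries labelled UPF2 deletion 63 of 293 (odds ratio 1.57, Fisher's exact p 0.00347) and in UPF3 69 of 292 (odds ratio 2.01, Fisher's exact p 3.34e-06). The authors' deposited tables gave the unspliced form of RPL28 log2 folds of 3.10, 2.96 and 3.11 and that of RPL22B 2.85, 2.65 and 2.69, where the spliced form of RPL22B had -1.82, -1.38 and -1.25. Within a gene the unspliced form lay above the spliced form in 224 of 254 pairs in UPF1, 210 of 251 in UPF2-labelled libraries and 208 of 247 in UPF3, with median differences of 0.74, 0.57 and 0.62. Spliced forms rose less often than other features, at 13 of 282, 18 of 284 and 10 of 284 (odds ratios 0.302, 0.369 and 0.221; Fisher's exact p 1.10e-06, 4.38e-06 and 6.33e-09). Pseudogenes rose often, at 8 of 17, 10 of 17 and 9 of 18 (odds ratios 5.77, 8.06 and 6.32; Fisher's exact p 0.000813, 4.31e-05 and 0.000255), among them SDC25 and FLO8, which carries a stop codon in the reference strain. Long noncoding RNAs such as ICR1 (2.85, 2.66 and 2.63) and RME2 (3.04, 2.84 and 2.81) rose in the authors' deposited tables, within a class in which 7 of 19, 5 of 19 and 7 of 19 rose (Fisher's exact p 0.00895, 0.193 and 0.0101).

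Coding genes without introns rose more often than other features, at 809 of 5581, 938 of 5582 and 853 of 5581. Odds ratios were 1.51, 1.81 and 1.84 (Fisher's exact p 1.32e-06, 6.90e-13 and 1.82e-12). The others include transfer, small nucleolar and ribosomal RNAs. None of these rose, which enlarges the excess by an untested amount. Reading frames outside the reference annotation rose less often, at 64 of 641, 69 of 647 and 56 of 644 (odds ratios 0.695, 0.646 and 0.574; Fisher's exact p 0.00635, 0.000687 and 5.60e-05). With a minimum mean of 10 the former difference was lost in UPF1 alone (Fisher's exact p 0.246) and the latter in each group (Fisher's exact p 0.0573, 0.112 and 0.364). Joined reading frames rose at 15 of 44, 13 of 45 and 9 of 45 and fell at 1, 8 and 7 (odds ratios of rising 3.37, 2.29 and 1.57; Fisher's exact p 0.000384, 0.019 and 0.273), and YPL060C-A rose in each. The UPF1 excess was lost at 2-fold (Fisher's exact p 0.0643) and the UPF2-labelled one under all 3 alternatives run.

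The DCP1 deletion asked what accumulates when caps are not removed. There, 1409 features were higher (53.8%) and 1209 lower. With equal totals 67.1% of them lay above the wild type, and a new test of all features gave 3816 higher and 217 lower. The authors' deposited table put TMA10, a ribosome-associated protein gene, at a log2 fold of 6.59, the heat shock genes HSP12 and HSP26 at 5.30 and 4.32, FDH2 (a pseudogene with near-identical copies) at 5.30 and the pyruvate carrier gene MPC3 at 5.03. ADH2, the alcohol dehydrogenase of ethanol use, had 4.78 and POT1 of fatty acid oxidation 4.74 in the authors' deposited table, with YGR259C at 5.66, ECM13 at 4.89 and YCL048W-A at 4.2. All 4 genes of the 2-micron plasmid fell (0 in DCP2-labelled libraries): the authors' deposited table gave REP1 -8.03, FLP1 -7.92 and REP2 -6.57. Plasmid loss was not tested. DCP1 itself (-7.36), the transposon reading frame YDR365W-B (-6.61, near-identical copies), SET6 (-3.99), IMD1 (-3.91), IMD2 (-3.68) and SNR59 (-3.38) were the other large decreases in the authors' deposited table.

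The libraries labelled DCP2 deletion, in which DCP2 RNA was raised, had 1073 features higher (55.2%) and 872 lower. With equal totals 64.1% of them lay above the wild type, and the new test gave 3483 higher and 139 lower. Mating-type genes stood out. The authors' deposited table gave the alpha pheromone genes MF(ALPHA)1 and MF(ALPHA)2 log2 folds of 11.25 and 5.53, MATALPHA1 8.28 with the same values for its silent copy HMLALPHA1, and the a-factor receptor gene STE3 4.81. It also gave HMRA1 -8.36, the a-factor genes MFA2 and MFA1 -7.65 and -6.70, AGA2 -5.90, the protease gene BAR1 -5.72 and ASG7 -4.80 in the authors' deposited table. Of 7 a-specific genes 7 fell and of 4 alpha-specific genes 4 rose (list medians -5.72 and 5.17, adjusted p 1.37e-39 and 1.05e-23). Outside the mating-type lists, the authors' deposited table had TMA10 at 5.72, YGR259C at 5.08, HSP12 at 4.47, ADH2 at 4.07 and ECM13 at 4.0, and YML039W at -10.15, RDT1 at -7.27, FET3 at -5.31 and YLR256W-A at -4.80. YML039W and YLR256W-A have near-identical copies. Without the genes of both mating-type lists 1069 features were higher and 865 lower.

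Genes of chromosome III stood higher in the same libraries, a pattern looked for after the values were seen. The median of its 145 genes lay 0.82 above that of all 5376 genes on the log2 scale, or 1.76-fold, with 129 of 145 above the median of all genes. The other chromosomes lay between -0.09 and 0.03 in these libraries, and all chromosomes in the other 5 strains between -0.17 and 0.12. Of 175 tested features of chromosome III, 102 were higher and 5 lower, beside 35 higher in DCP1. Without this chromosome 971 features were higher and 867 lower. The chromosome carries HIS4, LEU2, CDC39 and PET18 among listed genes, so their folds in the libraries labelled DCP2 deletion move with it.

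**Figure D3:**
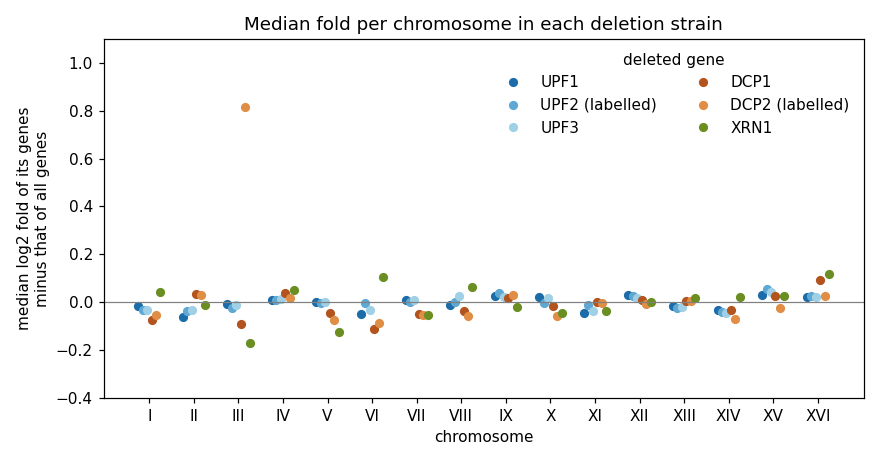
Median log2 fold of the genes of each chromosome minus that of all genes (vertical axis), one dot per deletion strain, over the 16 nuclear chromosomes. Chromosome III lies at 0.82 in the libraries labelled DCP2 deletion, and every other dot lies between -0.17 and 0.12.

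The XRN1 deletion asked what accumulates when decapped RNA is not degraded. It had 1386 features higher and 1505 lower, 47.9% higher, with medians of 1.99-fold for the increases and 2.60-fold for the decreases. With equal totals 68.4% of the same features lay above the wild type and these medians turned to 4.39-fold and 1.18-fold, and the new test gave 4438 higher and 325 lower. The spacer ITS1-1 of the ribosomal RNA precursor, with the same values as its copy ITS1-2, rose by a log2 fold of 5.40 in the authors' deposited table. Next in the authors' deposited table were YHR073W-A (3.84), the unspliced form of YBL111C (3.71, near-identical copies), TMA10 (3.67), MPC3 (3.40) and YGR259C (3.18). The authors' deposited table gave MTH1, a regulator of glucose transport, 2.92, ADE2 2.88 and the unspliced form of YRA1 2.79. Beyond XRN1 at -8.18, the authors' deposited table listed YLR256W-A at -11.89, YML039W at -9.64, YDR365W-B at -6.35 (these 3 with near-identical copies) and BSC1 at -5.56. Transfer RNAs followed, with the unspliced forms of SUF8, tP(UGG)N1 and tP(UGG)N2 at -8.43 and SUF4 and SUF6 at -5.55, all near-identical copies, in the authors' deposited table. Features with a mean of at least 50 that passed with 0 in 1 group have no finite fold and are in no ranking. At 0 in the authors' deposited tables were YHR054C and the unspliced form of RPS22B in the decay strains, SNR59 and YAR010C in XRN1, YRF1-3 and YRF1-7 in UPF1 and UPF3, YPR203W in UPF1, and unspliced YEL076C-A in the UPF groups and DCP2-labelled libraries. At 0 in the wild type were unspliced YER160C, which passed in UPF2-labelled and DCP2-labelled libraries and XRN1, and unspliced HFM1, which passed in DCP1.

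Short stable RNAs and mitochondrial transcripts were lower in XRN1. Of 322 transfer RNAs 140 were lower, with a median of -4.11 and of -2.97 with equal totals, and of 82 small nucleolar and nuclear RNAs 81 were lower, with a median of -3.43 and of -2.29 with equal totals. In the authors' deposited table SNR18 had -3.85, the unspliced form of SNR17B -3.78 and SNR128 -3.13, and the ribosomal RNA precursor RDN37 had -4.04. The same class had 36 lower in DCP1 and 31 in the libraries labelled DCP2 deletion, and 15 and 7 transfer RNAs were lower there. Of 15 listed mitochondrial genes 12 fell in XRN1 (14 adjusted over the list alone; median -2.14, or -1.0 with equal totals, adjusted p 6.92e-07), among them VAR1, OLI1, COX2 and COB. In DCP1 COX1 fell, and in the libraries labelled DCP2 deletion COX1, COB and the unspliced form of AI3, and the list was not called (adjusted p 0.656 and 0.338).

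Most features that rose in all 3 UPF strains rose in the decay strains as well. Of the 907, 614 rose in DCP1 (67.7%, against 12.3% of other features; odds ratio 14.9, Fisher's exact p 8.83e-269) and 13 were lower. In the libraries labelled DCP2 deletion 561 rose (61.9% against 7.91%; odds ratio 18.9, Fisher's exact p 2.91e-291) and in XRN1 548 (60.4% against 13.0%; odds ratio 10.2, Fisher's exact p 1.78e-201). Of these features 418 rose in all 3 decay strains, 161 in exactly 2, 147 in exactly 1 and 181 in none. In DCP1, DCP2-labelled and XRN1 order, the authors' deposited tables gave HIS3 log2 folds of 3.01, 2.75 and 1.55, ADE2 1.66, 1.53 and 2.88, AAD15 2.04, 2.60 and 2.33 and PET18, on chromosome III, 1.94, 2.87 and 2.14. Independent lists would have shared 174, 132 and 171 with the 907. Simulated no-effect lists of observed length had 70.8%, 62.7% and 70.4% of features common to 3 groups in the fourth too. They took features short of the threshold, so they cannot say how much of the 614, 561 and 548 comes from the shared wild type.

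In all 3 decay strains 675 features rose and 639 fell. Of these, 207 and 533 passed likewise in no UPF strain, which is no test of a difference. DCP1 and the libraries labelled DCP2 deletion shared 945 higher and 801 lower features, where independent lists would share 205 and 144, with r of 0.88 across features (0.497 simulated) and a covariance of 0.776 against 0.0263 simulated. DCP1 and XRN1 shared 848 higher and 871 lower (266 and 248 if independent; covariance 0.891 against 0.0274), and DCP2-labelled libraries and XRN1 719 and 683 (202 and 179 if independent; covariance 0.814 against 0.0291). UPF1 shared 635 higher features with DCP1, 578 with DCP2-labelled libraries and 567 with XRN1, with r of 0.60, 0.61 and 0.55 (0.494, 0.498 and 0.495 simulated) and covariances of 0.442, 0.409 and 0.495 against 0.0265, 0.0282 and 0.0293 simulated. UPF3 and XRN1 had r of 0.418 (0.498 simulated) but covariance of 0.356 against 0.0278. Simulated no-effect lists of observed length shared at most 522, 632 and 524 in the first 3 pairs and 491, 411 and 485 with UPF1. Part of each excess may come from the shared wild type.

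Difference tests found more features between decay strains than between UPF strains. DCP1 and DCP2-labelled libraries differed at 61 of 7145 features, 30 without chromosome III. HMRA1 was higher in DCP1 by 7.94 (SE 0.44, adjusted p 1.77e-70 in the test of the authors' folds), followed by MFA2, RDT1, MFA1 and AGA2, and MF(ALPHA)1, REP2, REP1 and FLP1 were lower by -8.09 to -7.66. DCP1 and XRN1 differed at 478 of 7073, among them ADH2 by 5.20 (SE 0.64) and OYE3 by 5.52 (SE 0.83) and, in the other direction, REP2 by -7.40 and FLP1 by -7.13. DCP2-labelled libraries and XRN1 differed at 371 of 7061, with STE3 at 5.96 (SE 0.50) and ITS1-1 at -6.49 (SE 0.72). UPF1 and the libraries labelled DCP2 deletion differed at 479 of 7121, with TMA10 at -5.61 (SE 0.35), HSP12 at -4.98 (SE 1.42) and ECM13 at -4.34, and UPF1 and XRN1 at 1105 of 7053, with BSC1 at 5.46 (SE 0.85), MPC3 at -3.64 (SE 0.46) and TMA10 at -3.56 (SE 0.35). At a correlation of 0.5 these 5 pairs differed at 206, 1442, 1317, 1242 and 2330. Of the 907 common features, by the first test, 122 were higher in UPF1 than in the libraries labelled DCP2 deletion and 5 lower, and 145 were higher in UPF1 than in XRN1 and 1 lower. At a correlation of 0.5, 311 and 354 of them differed.

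Glucose-repressed and stress-induced lists rose in the decapping strains. Of 30 glucose-repressed genes 24 rose in DCP1, 17 in the libraries labelled DCP2 deletion and 7 in XRN1, where HXT4 and FDH1 fell, but not adjusted over the list alone (adjusted p 3.47e-15, 1.25e-10 and 0.135). In DCP1, DCP2-labelled and XRN1 order, the authors' deposited tables gave the lactate carrier gene JEN1 3.71, 3.27 and 1.92 and the glucose carrier gene HXT6 3.28, 3.46 and 1.17, and POX1 of fatty acid oxidation rose in the first 2. Of 57 stress-induced genes 43, 31 and 20 rose (45, 34 and 21 adjusted over the list alone; adjusted p 2.91e-18, 2.71e-08 and 0.0388, the last with an adjusted p of 0.229 at a correlation of 0.05), and 10 fell in XRN1 (11 adjusted over the list alone). ALD3 and the glycogen gene GPH1 rose and DDR48 fell in each. Of 24 heat shock genes 9, 5 and 3 rose and 4, 4 and 10 fell (12 in XRN1 adjusted over the list alone; adjusted p 0.325, 0.925 and 0.0845), and the chaperone gene SSA2 fell in each. Of 24 cell wall genes 7, 6 and 1 rose and 2, 1 and 6 fell (adjusted p 0.36, 0.279 and 0.318).

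Most of the lists that rose in the UPF strains were also called up in a decay strain. Of 25 classic NMD substrates 14, 16 and 18 rose (14, 16 and 19 adjusted over the list alone; adjusted p 7.96e-06, 1.69e-06 and 3.63e-07). Of 12 telomere genes 8, 8 and 9 rose and RAP1 fell in each (RIF1 too in DCP1 adjusted over the list alone; adjusted p 0.00161, 0.000464 and 0.00036). The W303 markers ADE2, CAN1, HIS3 and TRP1 rose in each, LEU2, on chromosome III, rose in DCP2-labelled libraries, and URA3 fell in DCP2-labelled libraries and XRN1 (adjusted p 5.44e-05, 4.19e-05 and 0.00377). Meiosis genes rose at 16, 10 and 8 of 27 (18, 10 and 8 adjusted over the list alone; adjusted p 4.65e-07, 0.00068 and 0.05), and the list was not called in XRN1. Of 14 meiotic genes with introns 7, 3 and 4 rose (adjusted p 0.0215, 0.116 and 0.157), and the DCP1 call had an adjusted p of 0.0789 at a correlation of 0.05. The seripauperin list had 11, 8 and 5 higher (adjusted p 0.0409, 0.023 and 0.562; the first 2 had adjusted p of 0.172 and 0.128 at a correlation of 0.05), and TIR1 fell in each, to -4.18 in XRN1 in the authors' deposited table. Flocculation genes rose at 5, 5 and 4 of 7 (and AQY2 fell in DCP1 adjusted over the list alone; adjusted p 0.0213, 0.00479 and 0.356), the first with an adjusted p of 0.0515 at a correlation of 0.05. Without near-identical copies neither call passed (adjusted p 0.241 and 0.0731), while the water channel genes AQY1 and AQY2 of this list fell in XRN1. Nitrogen genes rose at 10, 7 and 9 of 23 and fell at 6, 2 and 2 (8 higher in DCP2-labelled libraries adjusted over the list alone; adjusted p 0.0918, 0.078 and 0.0106), and the XRN1 call had an adjusted p of 0.0737 at a correlation of 0.05.

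Of 20 genes of the G1 to S transition 7, 5 and 13 rose in the decay strains (adjusted p 0.0171, 0.021 and 1.86e-06; the first 2 had adjusted p of 0.0858 and 0.0965 at a correlation of 0.05). Of 40 spliceosome genes 7, 6 and 13 rose (adjusted p 0.362, 0.517 and 0.00486, the last with an adjusted p of 0.0787 at a correlation of 0.05). Genes with upstream reading frames rose at 8, 5 and 8 of 28 (9 in DCP1 adjusted over the list alone; adjusted p 0.24, 0.318 and 0.048, the last with an adjusted p of 0.187 at a correlation of 0.05). Of 26 decay factors 6, 8 and 8 rose (adjusted p 0.708, 0.149 and 0.999), EDC1, an enhancer of decapping, and DCS2 in each, and LSM7 fell in each. Respiration genes rose at 16 and 6 of 46 in DCP1 and DCP2-labelled libraries and 9 fell in XRN1 (4 in DCP2-labelled libraries and 6 in XRN1 adjusted over the list alone; adjusted p 0.0171, 0.225 and 0.0472; the first and last had adjusted p of 0.151 and 0.229 at a correlation of 0.05). The XRN1 median of -0.36 turned to 0.78 under equal totals.

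Ribosomal protein, glycolysis, translation factor, phosphate and ergosterol lists were called down in the decay strains. Of 138 ribosomal protein genes 120, 107 and 130 fell (124, 115 and 130 adjusted over the list alone; adjusted p 2.78e-30, 4.24e-21 and 9.69e-52), with medians of -1.12, -0.88 and -1.62, and of -0.35, -0.15 and -0.48 with equal totals. RPL15A fell and the unspliced form of RPL22B rose in each. Of 24 glycolytic genes 15, 15 and 18 fell (adjusted p 0.00149, 0.00134 and 1.44e-07), with medians below 0 also with equal totals (-0.49, -0.45 and -0.80). The aldolase gene FBA1 fell and HXK1 rose in each, as 1 of 3 risers in DCP1 adjusted over the list alone. Of 35 translation factors 25, 21 and 26 fell (26, 23 and 27 adjusted over the list alone; adjusted p 6.30e-09, 1.38e-07 and 1.11e-08). The medians in DCP2-labelled libraries and XRN1 turned to 0.03 and 0.23 under equal totals. Of 15 phosphate genes 11, 12 and 9 fell (adjusted p 3.77e-06, 4.60e-12 and 0.00446), and the XRN1 median turned from -0.88 to 0.26 under equal totals. Of 24 ergosterol genes 17, 5 and 16 fell (17 in XRN1 adjusted over the list alone; adjusted p 1.69e-05, 0.000648 and 2.10e-05), with the last 2 medians turning to 0.10 and 0.12 under equal totals.

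Further lists were called down in at least 1 decay strain, with medians that mostly turned with the scaling. Of 47 targets of Gcn4 25, 10 and 24 fell (25, 11 and 25 adjusted over the list alone; adjusted p 1.50e-05, 0.021 and 0.000212). Their medians of -0.54, -0.26 and -0.57 turned to 0.23, 0.47 and 0.57. Against random lists matched on mean the first and last did not pass (adjusted p 0.577 and 0.493) and the second turned to higher (adjusted p 0.0145). The second also had an adjusted p of 0.165 at a correlation of 0.05. Of 16 purine genes 10, 9 and 8 fell (10, 10 and 8 adjusted over the list alone; adjusted p 3.22e-05, 0.000374 and 0.0257). The XRN1 median of -0.59 turned to 0.55, with an adjusted p of 0.0965 at a correlation of 0.05. Of 14 pyrimidine genes 7, 5 and 8 fell (8, 6 and 8 adjusted over the list alone; adjusted p 0.0344, 0.139 and 0.136), the first with a median that turned from -0.55 to 0.22 under equal totals and an adjusted p of 0.106 at a correlation of 0.05. Of 24 sulfur genes 8, 10 and 16 fell (8, 10 and 17 adjusted over the list alone; adjusted p 0.0984, 0.0219 and 1.34e-05), the second with an adjusted p of 0.11 at a correlation of 0.05. The medians of -0.43 and -1.01 in DCP2-labelled libraries and XRN1 turned to 0.30 and 0.13. Of 10 histone genes 4, 2 and 6 fell (4, 1 and 8 adjusted over the list alone; adjusted p 0.424, 0.554 and 0.00462), and the XRN1 median turned from -0.64 to 0.50 under equal totals. Of 18 genes of the unfolded protein response 9, 6 and 9 fell (8 in DCP2-labelled libraries adjusted over the list alone) and INO1 rose (adjusted p 0.0248, 0.00249 and 0.0472; the first and last had adjusted p of 0.0997 and 0.154 at a correlation of 0.05). Their medians of -0.48, -0.50 and -0.49 turned to 0.29, 0.22 and 0.65. Of 84 ribosome biogenesis genes 17, 5 and 11 fell (15, 2 and 11 adjusted over the list alone; adjusted p 0.00149, 0.0445 and 0.284; the first 2 had adjusted p of 0.0859 and 0.275 at a correlation of 0.05). The medians of -0.37 and -0.23 in DCP1 and DCP2-labelled libraries turned to 0.40 and 0.50. Of 12 deadenylation genes CCR4, POP2, CDC39, PAN2 and PAB1 fell in DCP1, CCR4 and PAB1 in DCP2-labelled libraries and CDC36 and PAB1 in XRN1 (adjusted p 0.00882, 0.0175 and 0.751; the second had an adjusted p of 0.0605 at a correlation of 0.05). The first 2 medians of -0.48 and -0.46 turned to 0.30 and 0.27.

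The other lists were not called in the decay strains. These were iron (10, 10 and 10 higher of 27; adjusted p 0.185, 0.532 and 0.116), metal transport (adjusted p 0.957, 0.893 and 0.393; ALR2 rose in each, and ZRC1 fell in each but not in DCP2-labelled libraries adjusted over the list alone), DNA damage (adjusted p 0.414, 0.556 and 0.625; RNR2, RNR4 and HUG1 fell in each), pheromone response (adjusted p 0.666, 0.318 and 0.284; FIG2 and PRM1 rose in each, as 2 of 4 in XRN1 adjusted over the list alone) and regulated splicing (7, 7 and 8 lower of 20, or 8 in DCP1 adjusted over the list alone; adjusted p 0.362, 0.328 and 0.274). Proteasome (adjusted p 0.171, 0.0701 and 0.0519; RPN4, the regulator of these genes, rose in each, and of PRE3 and RPN1, which fell in DCP2-labelled libraries, 1 passed adjusted over the list alone), exosome and Ski (adjusted p 0.551, 0.944 and 0.397; RRP6 fell in DCP1, but not adjusted over the list alone), frameshift (adjusted p 0.843, 0.957 and 0.938; EST3 rose in each) and COS genes (adjusted p 0.848, 0.35 and 0.293; COS5 and COS7 rose in DCP2-labelled libraries, but not adjusted over the list alone) were not called either. The a-specific and alpha-specific lists were not called in DCP1 (adjusted p 0.153 and 0.121) or XRN1 (adjusted p 0.553 and 0.45), where SAG1 and MF(ALPHA)1 rose in both.

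Of the 136 list calls in all strains, 63 did not pass against random lists matched on mean, 72 passed in the same direction and 1, Gcn4 targets in DCP2-labelled libraries, in the other. In each UPF group those not passing were glucose-repressed genes, meiotic genes with introns, ergosterol, Gcn4 targets, proteasome, respiration and translation factors. Further ones were the G1 to S list in UPF1 and UPF2-labelled libraries, purine in UPF1, nitrogen in UPF1 and UPF3, deadenylation and COS genes in UPF2-labelled libraries and UPF3, decay factors in UPF1 and exosome in UPF3. In the decay strains they were translation factors in all 3, ribosomal protein, ribosome biogenesis, G1 to S and deadenylation in DCP1 and DCP2-labelled libraries, and Gcn4 targets, telomere and unfolded protein response in DCP1 and XRN1. Ergosterol and purine in DCP2-labelled libraries and XRN1, meiotic introns and pyrimidine in DCP1, meiosis, sulfur and seripauperin in DCP2-labelled libraries, and histones, nitrogen, phosphate, respiration and spliceosome in XRN1 were the rest. Without near-identical copies 8 calls were lost, stress-induced genes in UPF2-labelled libraries, UPF3 and XRN1, COS genes in UPF2-labelled libraries and UPF3, genes with upstream reading frames in XRN1 and the 2 flocculation calls. ALD3, COS4, COS5, COS7, DDI2, FDH1, FLO1, FLO9, HXT6, SSA2, TIF2, YAR010C, YEL076C-A, YER160C, YPL060C-A, YPR203W, YRF1-3, YRF1-7 and spliced tL(CAA)D also have such copies.

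**Figure D4:**
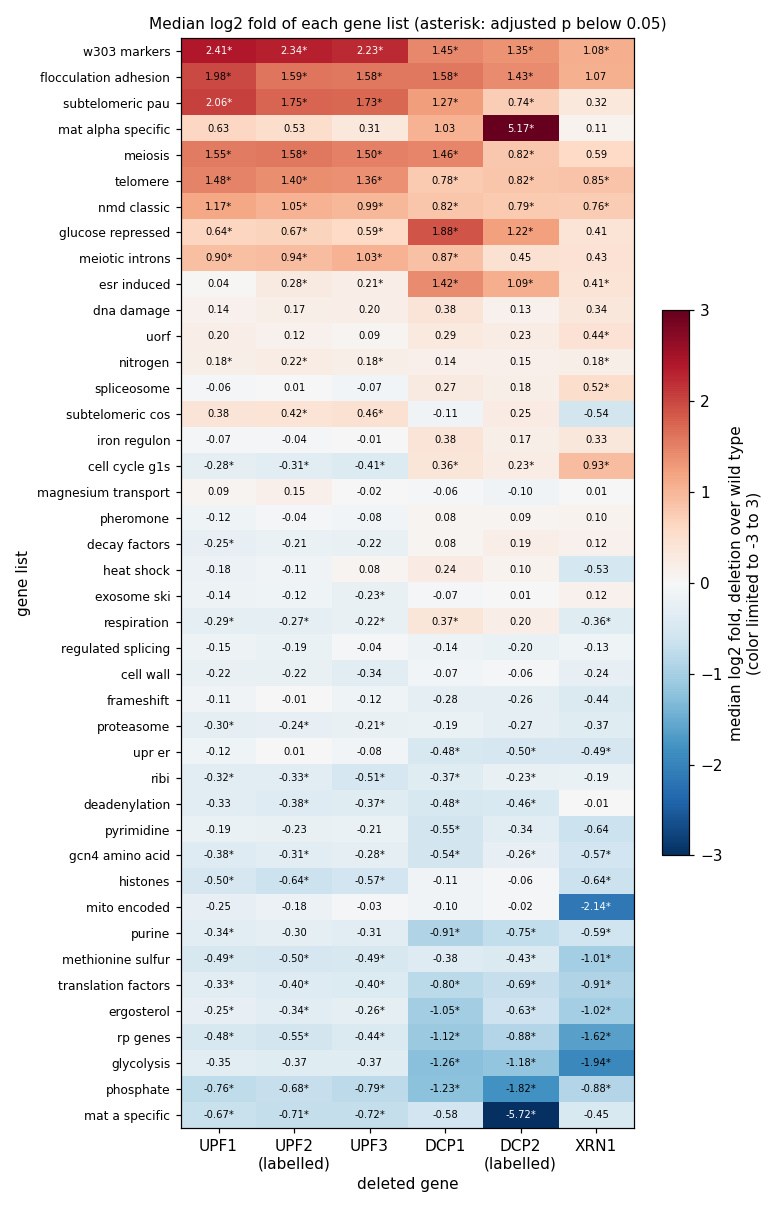
Median log2 fold of each of the 42 gene lists (vertical) in each deletion strain (horizontal), in color from blue (-3) over white to red (3), with an asterisk where the list test had an adjusted p below 0.05. W303 markers lie at 2.23 to 2.41 in the UPF strains and a-specific genes at -5.72 in the libraries labelled DCP2 deletion.

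Unspliced forms were not in excess among the increases of the decay strains. Of 294 in DCP1, 31 rose and 58 fell (odds ratio of rising 0.487, Fisher's exact p 7.46e-05), of 295 in the libraries labelled DCP2 deletion, 40 rose and 40 fell (odds ratio 0.918, Fisher's exact p 0.674), and of 292 in XRN1, 21 rose and 98 fell (odds ratio 0.324, Fisher's exact p 1.60e-08). Their median difference from the spliced form was 0.15, 0.24 and 0.25, and whether it differed from that of the UPF strains was not tested. The unspliced form of RPL28 had log2 folds of 2.17, 2.31 and 1.90 in the authors' deposited tables. Spliced forms fell at 123 of 283, 99 of 284 and 147 of 282. Pseudogenes rose at 10 of 17, 9 of 17 and 5 of 16 (Fisher's exact p 0.00033, 0.000228 and 0.203). Joined reading frames fell at 24, 30 and 30 of 45.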

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

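The tests of difference between strains reported in this part were planned, while all tests of the 3 explained patterns, except that on short coding genes, were chosen only after the result was seen. Pairs of strains were compared by the difference of the authors' folds, and the count of features that differed drew attention.

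UPF1 and the libraries labelled UPF2 deletion differed at 5 features, with YHR214C-B (near-identical copies) higher in UPF1 by 4.29 on the log2 scale (SE 0.30) and NAM7 lower by -7.56. UPF1 and UPF3 differed at 5, with UPF3 at 7.78 and NAM7 at -7.57. The UPF2-labelled libraries and UPF3 differed at 11, with UPF3 at 7.79 and YHR214C-B at -3.90 (SE 0.26). DCP1 and the DCP2-labelled libraries differed at 61, with HMRA1 at 7.94 and MF(ALPHA)1 at -8.09. The DCP2-labelled libraries and XRN1 differed at 371, with MF(ALPHA)1 at 8.88 and RDT1 at -8.12. DCP1 and XRN1 differed at 478, with YLR256W-A (near-identical copies) at 9.25 (SE 1.29) and DCP1 at -7.49. UPF1 and the DCP2-labelled libraries differed at 479, with RDT1 at 8.15 and NAM7 at -7.49. UPF1 and XRN1 differed at 1105, with YLR256W-A at 10.91 and NAM7 at -7.57.

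NMD2 and DCP2 RNA was raised in the libraries labelled with their deletion. Libraries of another deletion strain are argued against by the other deleted genes, at 68.8% of the wild type or more in both groups. Unchanged wild-type libraries are too, by at least 1283 changed features in each. A deletion that leaves part of the gene, or a plasmid copy, may account for the reads. Unspliced NMD2 stood at 1.18% of the wild type. A working copy is argued against: UPF2-labelled folds had r of 0.96 with UPF1, DCP2-labelled ones 0.88 with DCP1. Without values by position in a gene, the rest cannot be told apart.

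The libraries labelled DCP2 deletion had alpha-specific genes raised and a-specific genes lowered. Loss of silencing in an a strain is argued against by HMRA1 at a log2 fold of -8.36, and alpha cells mixed into an a culture by the median of -5.72 of the a-specific list. A strain of the other mating type is a candidate explanation, with a median of 5.17 for the alpha-specific list, and this is a hypothesis found and tested on the same data. The mating type of each strain is not given in the sources used here. An effect of the deletion itself on mating-type genes was not tested apart from it.

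Small nucleolar, small nuclear and transfer RNAs were lower in XRN1. One scaling factor per strain is argued against as the whole cause by the median of -2.29 that remained for small nucleolar and nuclear RNAs under equal totals. Loss of short RNAs alone is argued against by the median of -2.68 of 7 stable noncoding RNAs of at least 500 nucleotides, or -1.53 with equal totals. The 79 shorter ones had -3.46, so a part that depends on length stays open. A loss that also reached short messenger RNAs cannot be told apart from other effects, because 238 coding genes under 300 nucleotides lay -0.41 from longer genes of like mean, a small shift beside that of the noncoding RNAs. Differences in ribosomal RNA removal or library making between groups stay open as untested, as does an effect of the missing nuclease.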

How the results depend on the processing

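Scaling to equal totals, standard errors from features of like mean, and counts without the UPF2-labelled or DCP2-labelled libraries, mating-type genes, near-identical copies or chromosome III were chosen after seeing the data, and all other tests here were planned. The tables hold only group means, so leaving out each replicate, other splits of the samples, both count models and a count test without a filter were not run. No paired analysis was possible because the columns carry no replicate numbers. The number of features higher in all 3 UPF strains stayed within 1.5 times of 907 under all 9 alternatives run, from 662 with at least 2-fold change to 1277 with equal totals, and was 827 without near-identical copies. The shares of these features that rose in DCP1, DCP2 and XRN1 stayed above those of other features, within 57.1% to 72.7%, 50.8% to 65.2% and 45.8% to 65.7% over the alternatives run. Counts of changed features did not move by over 1.5 times with a minimum mean of 10 or with p adjusted over features in all tables. Of simulated changes of 1.5-fold with 3 libraries per group 22% were found by a normal test given the true spread, not by DESeq.

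For the values that moved, the cause was not tested unless a looser or stricter threshold is the alternative itself. Features lower in UPF1, UPF2 and UPF3 numbered 175, 429 and 324 at an adjusted p under 0.05, and 23, 42 and 36 at 0.001, where 574 were lower in DCP2. With at least 2-fold change they numbered 22, 25 and 23, with 808 higher and 598 lower in DCP1, 620 and 400 in DCP2 and 688 higher in XRN1. With centred folds of at least 1.5, 59 were lower in UPF2 and 55 in UPF3. With equal totals 14, 27 and 22 were lower in UPF1, UPF2 and UPF3 and 1851 higher in UPF2. The decay strains then had 3816 higher and 217 lower (DCP1), 3483 and 139 (DCP2) and 4438 and 325 (XRN1). The UPF2 and DCP2 counts here are those of the libraries so labelled.

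Differences between strains, in the order UPF1 and UPF2, UPF1 and UPF3, UPF2 and UPF3, DCP1 and DCP2, DCP2 and XRN1, DCP1 and XRN1, UPF1 and DCP2, UPF1 and XRN1, numbered 12, 12, 20, 206, 1317, 1442, 1242 and 2330 when the errors were given a correlation of 0.5 for the shared wild type. At an adjusted p under 0.05 the last 5 pairs numbered 113, 725, 911, 780 and 1771. With standard errors from features of like mean the first 6 pairs numbered 13, 22, 47, 100, 675 and 754. Without chromosome III DCP1 and DCP2 differed at 30. A minimum mean of 10 and centred folds moved none of the 8 counts by over 1.5 times.

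Of 136 list calls, 72 passed in the same direction against random lists matched on mean, which called 84 in all, and 90 remained without the UPF2-labelled and DCP2-labelled libraries, which leaves fewer tests. The Gcn4 targets in the DCP2-labelled libraries turned direction against random lists (adjusted p 0.0145). With a minimum mean of 10, 243 of 252 list results were the same, and without near-identical copies 244. Of the named features, 122 kept their call under 3 alternatives each, and 4 lost it with equal totals.

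Shares of higher features in classes moved as follows. Reading frames outside the annotation no longer differed from other features in UPF1 at an adjusted p under 0.05 (13.7% higher), a minimum mean of 10 (18.7%) or at least 2-fold (9.83%). The same held in UPF2 at 20.2% and 10.5% with the last 2, and in UPF3 at 17.0% and 8.70%. Coding genes without introns did not differ in UPF1 with a minimum mean of 10 (15%). Joined frames did not differ in UPF1 at 2-fold (20.5%) and in UPF2 at 28.9%, 28.9% and 20% under the 3 alternatives. Noncoding RNAs rose more often than others in UPF2 with a minimum mean of 10 (41.2%) and in DCP2 at 2-fold (26.3%), while spliced forms in DCP1 rose less often under the 3 alternatives (17.0%, 15.1% and 6.01%).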

Other observations

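The tests on codon content and coding length were planned, and those on the unspliced forms of ribosomal protein genes and on chromosome III were chosen only after the result was seen. The 710 coding genes among the features higher in all 3 UPF strains, the UPF2-labelled libraries included, used fewer optimal codons than other genes, where an optimal codon is the one most used for its amino acid in 138 ribosomal protein genes. Their median was 36.3% optimal codons against 38.0% in sets of genes matched on the mean in the UPF1 deletion, at percentile 0 of 10000 sets. Matched on the wild-type mean instead, the sets had a median of 36.8% and the genes stood at percentile 0.37. Lower codon optimality may therefore be a property of these genes, as a hypothesis, and the size of the difference was small. Shorter coding regions are argued against: the median coding length was 1242 nucleotides against 1191 in sets matched on the mean in UPF1 (percentile 91.55), and against 897 in sets matched on the wild-type mean (percentile 100).

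Unspliced forms of ribosomal protein genes were among the common increases more often than those of other genes. Of 102 ribosomal protein genes with such a form 27 had it higher in all 3 UPF strains (26.5%), among them RPL28 and RPL22B, against 29 of 190 other genes (15.3%; odds ratio 2.0, two-sided Fisher's exact p 0.0284). The median wild-type mean of these forms was 1267 for ribosomal protein genes and 127 for the others, so deeper counting of the former may explain part of the difference, and this was not tested apart.

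An extra copy of chromosome III is a candidate explanation for the higher RNA of its genes in the libraries labelled DCP2 deletion. The 5 segments of 29 genes along the chromosome had medians of 0.82, 0.81, 0.96, 0.77 and 0.78 above that of all genes. No segment was spared. A scaling or composition effect on all chromosomes is argued against by the other chromosomes, the highest of which lay at 0.031. A decapping effect on these genes is argued against by DCP1, where the chromosome lay at -0.093, though RNA of mating-type genes differed between them too. DNA copy number was not analysed here, and the mating-type locus lies on the same chromosome.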
